A study of Mus musculus with 2 samples.

How the data were processed

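Total RNA of C57BL/6 nasal mucosa was hybridised to 2 Affymetrix Mouse Gene 2.0 ST arrays, 1 for papain and 1 for PBS, both at day 3, per the labels. The design text says that 4 samples were combined into a specimen. The deposited values are log2 signals per transcript cluster, a scale read from the values themselves: the median was 5.70 in the papain array and 5.64 in the PBS array. Transcriptome Analysis Console 4.0 is named in the submitters' processing notes. The background correction, summarisation and normalization behind the log2 values that the authors deposited are not given in the sources used here. A normalization that equalised the arrays would hide any difference in total RNA between the specimens, so each ratio is relative to the bulk of probe sets.

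Of 41345 transcript clusters, 23521 carried 1 gene symbol, 1814 several and 16010 none in the annotation used here, and only those with 1 symbol were named. The gene IDs of 23328 named clusters were found in a RefSeq gene table, and 0 of these had a different symbol there. For a gene with several probe sets the one with the highest mean signal was taken, which gave 22180 genes. The log2 ratio was the papain value minus the PBS value. Genes were counted at a 2-fold threshold when the higher of their 2 values reached the median of all named genes, a log2 signal of 6.29, which 11691 genes did. Counts within lists and families used all measured members without this floor unless stated. Background level was the median signal of 33 genes of other tissues, a set chosen after first ratios had been seen and before its signals were. No test, p-value or SD between replicates could be computed with 1 array per group, and the number of arrays limits the precision. The SD of 1 probe set's log2 ratio, from genes with repeated probe sets, was 0.32.

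Lists of 14 pathways and 25 cell types were fixed before the data were examined, and 394 of their 437 genes were measured. Each list's median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of mean signal, and its percentile describes these arrays only, since genes are not replicates. Receptor and antigen receptor families were defined by symbol prefix. Genes that share a prefix without being gene segments, such as Tradd, were left out of the T cell receptor family, and Igh-VS107 was added to the immunoglobulin segments. Both corrections were made after a first list of named genes had been seen, and the second put Calb1 in the place of Igh-VS107 among the 10 lowest ratios. Immunoglobulin segments, 21 genes, had a median log2 ratio of -0.51 with 2 genes at least 2-fold higher and 4 lower, and 8 T cell receptor segments had a median of 0.22 with none past 2-fold. The median signals of both these families were under background level in both arrays.

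The genes named were the 10 highest and 10 lowest ratios above the floor, without predicted genes, small RNAs and these families, up to 4 members of each list with the largest ratio in either direction, those past 2-fold first, and Il33, Il1rl1, Il5, Il13, Ocln, Tjp1, Cldn1 and Muc5ac whatever their values. Alternatives were quantile normalization, setting the median ratio to 0, loess of the ratio on the mean signal with a span of 0.3, averaging probe sets, no floor or a floor at the 75 percentile, thresholds of 1.5-fold and 3-fold, members above the floor only, leaving out families, and unmatched random lists. The median log2 ratio of genes above the floor was -0.10 as deposited and -0.02 after loess.

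The counting and list steps were tested on simulated data for the papain and PBS comparison, with 200 of 22180 genes changed. The simulated noise was independent between genes. It had 1 SD at all signals, 0.22 per array, taken from a robust spread of these same ratios. All 50 genes raised 3-fold, all 50 raised 6-fold, 47 of 50 lowered 3-fold and 7 of 50 raised 1.5-fold passed the 2-fold threshold, as did 15 of 11491 unchanged genes. The measured ratios above the floor had an SD of 0.495, any true differences included. The 15 of 11491 is therefore no false positive rate for these arrays. Of 1000 lists of 20 unchanged genes, 954 lay inside the central 95% of their random lists. Their genes varied independently, which those of a pathway or cell type need not do. The number of such lists was raised to 1000 after smaller draws had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.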

Results

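Gene expression in mouse nasal mucosa was measured 3 days after papain and after phosphate-buffered saline (PBS), per the sample titles. Papain is a plant cysteine protease used as an allergen model, and PBS is the vehicle control. The animals were C57BL/6 mice. Each group was 1 Affymetrix Mouse Gene 2.0 ST array, and the design text says that 4 samples were combined into a specimen, without saying whether the 4 were counted per array. The 2 arrays correlated with r = 0.967 across 41345 transcript clusters, a correlation across probe sets within this pair of arrays. With 1 array per group, no difference given here has a replicate check, no test was possible, and the number of arrays limits the precision. All values are log2 signals, and ratios are papain over PBS. Background level is used here for the median signal of 33 genes of other tissues, 4.92 in the papain array and 4.88 in the PBS array. A ratio with either signal under it is one of array signals and no measure of the fold in transcript. These 33 genes also read above their median, with a 95 percentile of 6.98 over both arrays. A fold whose lower signal lies between background level and 6.98 is of uncertain size, and such folds are not marked one by one. The study title names IL-33, innate immunity and the epithelial barrier, and the comparison addresses how the mucosa differed after the protease.

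The largest differences between the arrays lay in vomeronasal receptors, the pheromone receptors of sensory neurons in the vomeronasal organ. Of 177 family 1 receptors (Vmn1r), 113 were at least 2-fold higher in the papain array and 0 were lower, with a median ratio of 2.72-fold. Of 112 family 2 receptors (Vmn2r), 87 were at least 2-fold higher and 1, Vmn2r71, was lower with both signals under background, with a median ratio of 5.71-fold. Vmn1r37 was 60.9-fold higher, at a log2 signal of 10.61 against 4.68, and Vmn2r51 was 49.3-fold higher, at 8.21 against 2.59. In the PBS array 10.7% of the receptors of both families exceeded background level, against 57.1% in the papain array, so most of these folds, those of Vmn1r37 and Vmn2r51 included, have a denominator under it. Genes of other tissues also exceed this level, their own median, so 57.1% is no share of receptors detected. Past the 95 percentile of those genes, 6.98, lay 24.2% of the receptors in the papain array and 0.692% in the PBS array. Members of these families share sequence, which leaves the value of a single receptor uncertain.

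**Figure D1:**
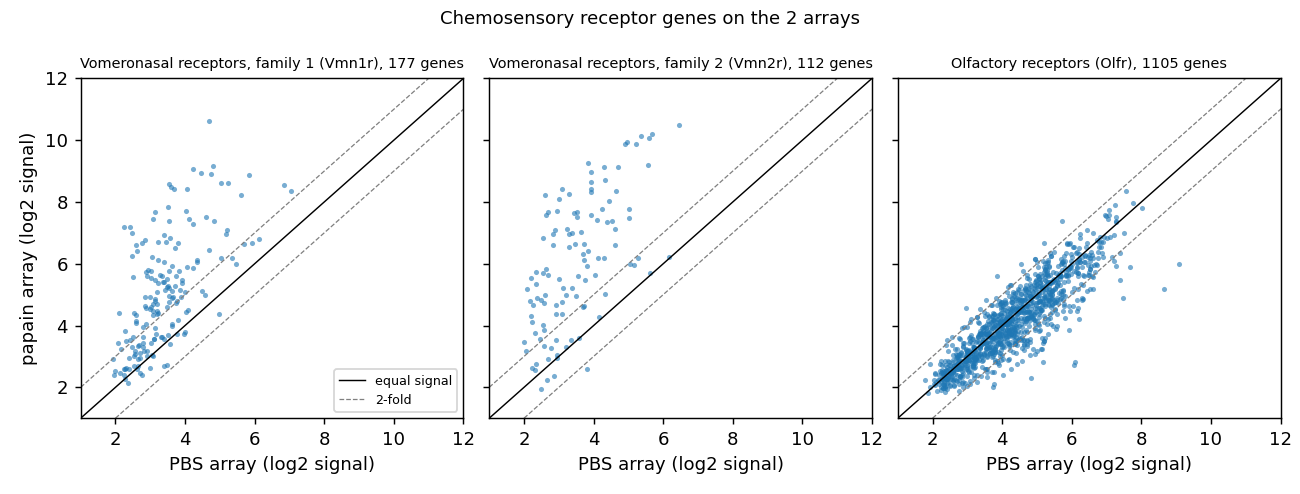
Log2 signal of each receptor gene in the papain array (vertical axis) against the PBS array (horizontal axis), 1 point per gene, for family 1 and family 2 vomeronasal receptors and olfactory receptors. The solid line marks equal signal and the dashed lines mark 2-fold; 113 of 177 Vmn1r and 87 of 112 Vmn2r genes lie at or above the upper dashed line, and 95 of 1105 olfactory receptors lie at or below the lower one.

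Other genes of vomeronasal neurons were higher in the same array. All 5 measured vomeronasal neuron markers had ratios above 0, and 1 of them was past 2-fold. Their median log2 ratio was 0.56, at the 99.95 percentile of random lists matched on mean signal, with an interval from resampling genes of 0.10 to 3.35. Calr4 was 10.2-fold higher. Trpc2, the cation channel of vomeronasal transduction, had a log2 ratio of 0.83. Gnao1, the G protein subunit of neurons that express family 2 receptors, had 0.56, and Meis2 had 0.29. Gnai2, another G protein subunit gene of the list, named after its value was seen, had only 0.10. H2-M1 and H2-M10.5, nonclassical class I histocompatibility genes of vomeronasal neurons, were 14.7-fold and 8.22-fold higher. The PBS signals of Calr4, H2-M1 and H2-M10.5, at 4.59, 3.31 and 4.43, were under background too.

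Olfactory receptors went apart gene by gene. Of 1105 Olfr genes, 21 were at least 2-fold higher and 95 at least 2-fold lower in the papain array, and their median log2 ratio was -0.11. Their median signals, 4.08 in the papain array and 4.24 in the PBS array, were under background, so most of these ratios are no measure of transcript. Only 93 of the 1105 were above the floor, 2 of them at least 2-fold higher and 15 lower. In all, 10.5% of them differed at least 2-fold, against 1.69% of genes of like signal outside the receptor families. The PBS over papain ratio was 10.9 for Olfr15, 10.2 for Olfr293, 9.52 for Olfr1383 and 8.62 for Olfr124, while Olfr341 was 3.34-fold higher in the papain array. The lower signals of Olfr293, Olfr1383 and Olfr341, at 2.72, 2.84 and 3.86, were under background. Olfactory sensory neuron markers had a median of -0.27, at the 1.94 percentile, with 1 of 11 members, S100a5, past 2-fold at -1.07. Cnga2, a subunit of the olfactory transduction channel, had -0.57 and the olfactory G protein gene Gnal had -0.47, while Rtp1, a receptor transport protein gene, had 0.45. Immature olfactory neuron and progenitor markers had a median of 0.18, at the 97.96 percentile, with Gng8 at 0.99, Ebf1 at 0.57, Stmn2 at 0.46 and Neurog1, under background in both arrays, at -0.25. Gap43, named after its value was seen, had 0.01, and the vomeronasal neuron markers, with a median of 0.56, were higher in the same array. This percentile was 92.2 with averaged probe sets and 93.1 against unmatched lists, both inside the central 95%.

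The list of genes that respond to IL-4 and IL-13, the cytokines of type 2 immunity, had a higher median in the papain array, beside the vomeronasal genes given above. Of 17 measured members, with no floor applied, 6 were at least 2-fold higher, 0 were at least 2-fold lower and 11 lay within 2-fold, 5 of the 17 with ratios below 0. The median log2 ratio was 0.47, above all 10000 random lists, with an interval from resampling genes of -0.04 to 1.18. Chil4 and Chil3, chitinase-like proteins, were 17.3-fold and 4.08-fold higher, the latter from a PBS signal of 4.65, under background. Retnla, which encodes a secreted protein of alternatively activated macrophages, read 6.07 after papain, under the floor, and 2.70 after PBS, under background, so no fold is given for it. Clca1, a secreted goblet cell protein, was 3.58-fold higher, a fold of uncertain size because its PBS signal of 6.03 was under 6.98. Itln1 and Fcgbp, named after their values were seen, were 2.26-fold and 2.09-fold higher, and Slc26a4, named likewise, had a log2 ratio of -0.55. Type 2 cytokines and chemokines had ratios above 0 for all 9 measured members, with a median of 0.55 at the 99.98 percentile, and none reached 2-fold. Ccl8 had a log2 ratio of 0.93, Ccl11, an eosinophil attractant, 0.60 and Il13 0.29. Only 2 of the 9 genes were above the floor of 6.29, the median of all named genes. Il4 and Il9 were under background in both arrays, so their ratios are not given, and Il5, at 0.55, read 5.16 against a PBS signal of 4.61 under background. The list median was the ratio of Il5 itself, so the median and its percentile rest in part on ratios that are no measure of transcript. Ccl17, Ccl24 and Ccl22, above background in both arrays and named after their values were seen, had 0.15, 0.07 and 0.04.

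The list of alarmins, cytokines that epithelium releases on damage, and their receptors showed no common direction. The 8 measured members of that list, alarmin and receptor genes together, had a median log2 ratio of -0.02, at the 47.54 percentile. Of these, 4 were above 0 and 4 below. Of the alarmin genes, Il33 had -0.54, with signals of 9.79 after papain and 10.33 after PBS. Il18 had -0.17, Il25 0.23 and Tslp, named after its value was seen, 0.16. The receptor gene Il18r1 had 0.27. The IL-33 receptor gene Il1rl1 was not analysed here, because no probe set used here carried its name alone.

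Genes for secreted products of epithelium and glands differed in both directions. Mucin and goblet cell genes had a median of 0.22, at the 99.86 percentile, with none of 12 members past 2-fold and an interval from resampling genes of -0.11 to 0.28. Muc5ac, a major airway mucin, had 0.61, Muc16 -0.54, Tff1 0.49 and Muc5b 0.32. Antimicrobial secreted proteins had a median of 0.17, at the 99.77 percentile and an interval of -0.13 to 0.29, with 1 of 19 past 2-fold, the lysozyme gene Lyz1 at 1.15. Lcn2, an iron-withholding protein, had 0.90, and Dmbt1 had 0.61. Nasal gland secretory genes had a median of 0.17, at the 99.65 percentile and with an interval of -0.05 to 0.95, with 4 of 14 members at least 2-fold higher and 1 lower when no floor was applied. The median was 0.03 among the 12 members above the floor, and the percentile was 96.95 against unmatched lists, inside the central 95%. Bpifb9b was 26.8-fold and Bpifb9a 18.8-fold higher, while Odam and Bpifb5, both under the floor, had PBS signals of 3.99 and 4.88, under background, so no fold is given for them. Bpifb3 had a PBS over papain ratio of 2.93. The other 9 members lay within 2-fold, among them Obp1a at -0.07 and Obp2a at 0.06, both named after their values were seen. For the Bpifb9 genes, a response to papain was not separated from a difference between the specimens, vomeronasal tissue included.

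None of the measured members of the junction and keratinization lists reached 2-fold. The 19 tight and adherens junction genes had a median of -0.05, at the 72.1 percentile, and this median became 0.01 after loess. Cldn8 had -0.82, Cldn3 -0.48, Cldn4 -0.44 and Cldn18, under background in both arrays, 0.38. Of the junction genes named in advance, Ocln had 0.09, Tjp1 0.08 and Cldn1 -0.28. The 20 measured members of the keratinization and cornified envelope list had a median of -0.25 at the 0.55 percentile and an interval of -0.38 to 0.06, from Krt17 at -0.94 to Sprr1b at 0.93, with Lor at -0.65 and Sprr3 at -0.63. Sprr2b, a cornified envelope gene outside that list and named after its value was seen, went the other way and was 4.92-fold higher, at 8.53 against 6.23. Sprr2a3, a planned member of the list, is missing from these values because its clusters also named other genes. Those of its clusters that were above the floor and past 2-fold were higher in the papain array, with log2 ratios from 2.02 to 3.54.

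Lists of stromal and ciliated cells were lower in the papain array. All 9 ciliated cell markers had ratios below 0, with a median of -0.45 at the 0.09 percentile. Rsph1 had -0.61, Tppp3 -0.59, Foxj1, the transcription factor of motile cilia, -0.54, and Ccdc40 -0.45. All 7 fibroblast markers were below 0, with a median of -0.38 at the 0.71 percentile, and Col1a2 had -0.78, Pdgfrb -0.62, Col6a1 -0.56 and Dcn -0.38. Cartilage and bone markers had a median of -0.49, below all random lists, with Acan at -0.82, Sp7 at -0.81, Bglap at -0.68 and Dmp1 at -0.57. The interval of this median from resampling genes reached 0.19, and Matn1, its PBS signal under background, and Col2a1, both named after their values were seen, had 0.54 and 0.19. Extracellular matrix and remodelling genes had a median of -0.32 at the 0.14 percentile, with Mmp9 and Lox both at -0.81, Tnc at -0.63 and Col1a1 at -0.60, while Mmp12 and Mmp10, named likewise, had 0.46 and 0.38. None of the 38 genes in these 4 lists reached 2-fold.

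Cell cycle genes had a median of 0.26, above all random lists, with Top2a at 0.67, Aurka at 0.46 and Ccna2 at -0.53, and with Birc5 under background in both arrays. Interferon-stimulated genes had a median of 0.20 at the 98.92 percentile and an interval of -0.11 to 0.48, with Oasl2 at 0.63, Zbp1 and Ifit1 at 0.61 and Isg15 at 0.48. The remaining pathway lists were NF-kB cytokines and chemokines with a median of 0.10, cystatins and stefins with 0.16, and MHC class II genes with 0.15, all inside the central 95% of their random lists. Among members above the floor, the NF-kB median turned to -0.12 and that of cystatins and stefins to -0.24. Eicosanoid synthesis genes had 0.20 at the 99.49 percentile and an interval of -0.31 to 0.38, a median that turned negative at -0.03 when probe sets of a gene were averaged and whose percentile was 91.2 after loess. Alox12e, a lipoxygenase gene, was 3.34-fold higher and was the 1 member of that list past 2-fold.

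**Figure D2:**
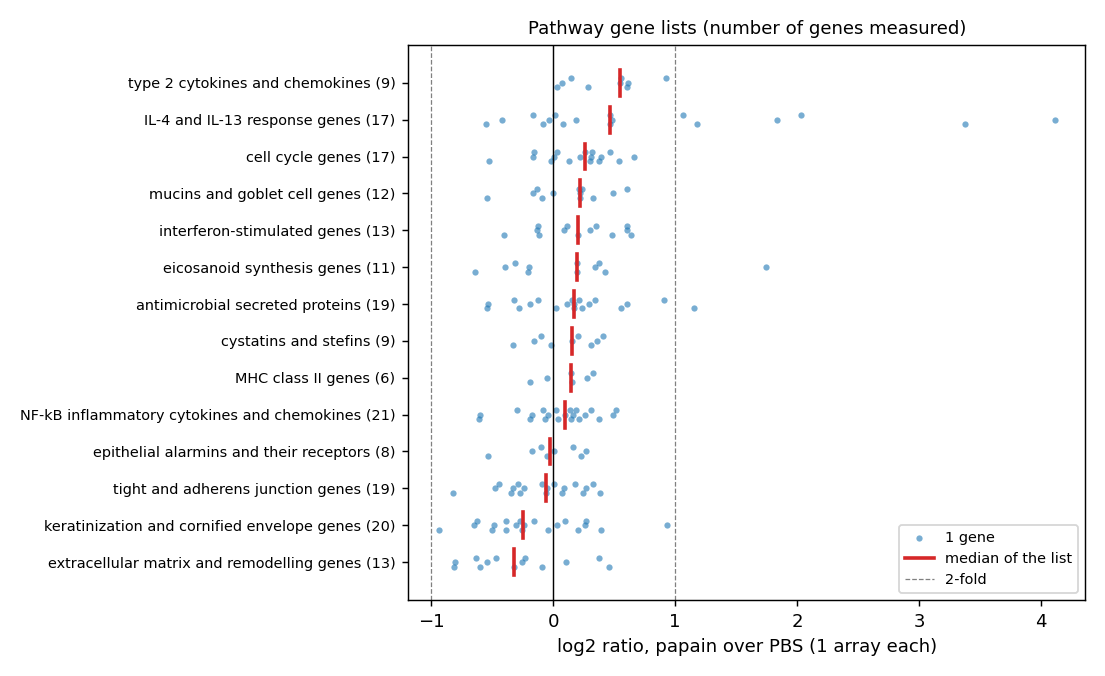
Log2 ratio of papain over PBS for each measured gene of the 14 pathway lists, 1 array per group, with the number of genes in parentheses, the list median as a red bar and 2-fold as dashed lines. The IL-4 and IL-13 response list has 6 genes beyond 2-fold, up to 4.11, while junction genes spread around 0 with a median of -0.05.

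The medians of the leukocyte marker lists over all measured members lay between -0.05 and 0.16. Few members were above the floor in several of them, such as 1 of 9 T cell markers and 0 of 7 NK cell markers, so these medians rest largely on dim genes. Eosinophil markers had a median of 0.16, with 0 of 6 above the floor, and Siglecf had 0.38 and Epx, with a PBS signal under background, 0.29. Macrophage and monocyte markers had 0.03, with Cd14 at -0.52 and Adgre1 at 0.33. Neutrophil markers had 0.06, and 1 of 10, the chemokine receptor Cxcr2, was 2.40-fold higher, while Ly6g was under background in both arrays. The 4 neutrophil markers above the floor, Cxcr2 included, had ratios from 0.09 to 1.26. T cell markers had -0.04 and B cell and plasma cell markers -0.05, with Jchain at -0.84, its papain signal under background, and Ighm, the 1 member above the floor, at -0.56. The 7 probe sets of Ighm ran from -0.77 to 0.31. The 21 immunoglobulin segments had a median of -0.51, below all random lists, with 4 at least 2-fold lower and 2, among them Igkv8-30, at least 2-fold higher from PBS signals under background. Their median signals, 4.78 after papain and 4.48 after PBS, were under background too. Of the 6 segments above the floor, 3 were at least 2-fold lower and 0 higher. The medians of mast cells and basophils at 0.00, dendritic cells at 0.02, group 2 innate lymphoid cells at -0.02, NK cells at 0.08, basal cells at -0.02 and tuft and microvillar cells at 0.07 each changed sign in at least 1 alternative setting. Among other cell types, sustentacular cells had -0.15, endothelial cells -0.15, ionocytes -0.13, glia and Schwann cells -0.31, adipocytes -0.24, skeletal muscle 0.25, and the single erythroid gene measured, Slc4a1, 0.42. Of the 39 lists, 10 lay above and 6 below the central 95% of their random lists. By chance 1.95 would lie outside it if list members varied independently. Genes of a pathway or cell type can vary together, so these counts are no measure of an excess over chance.

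**Figure D3:**
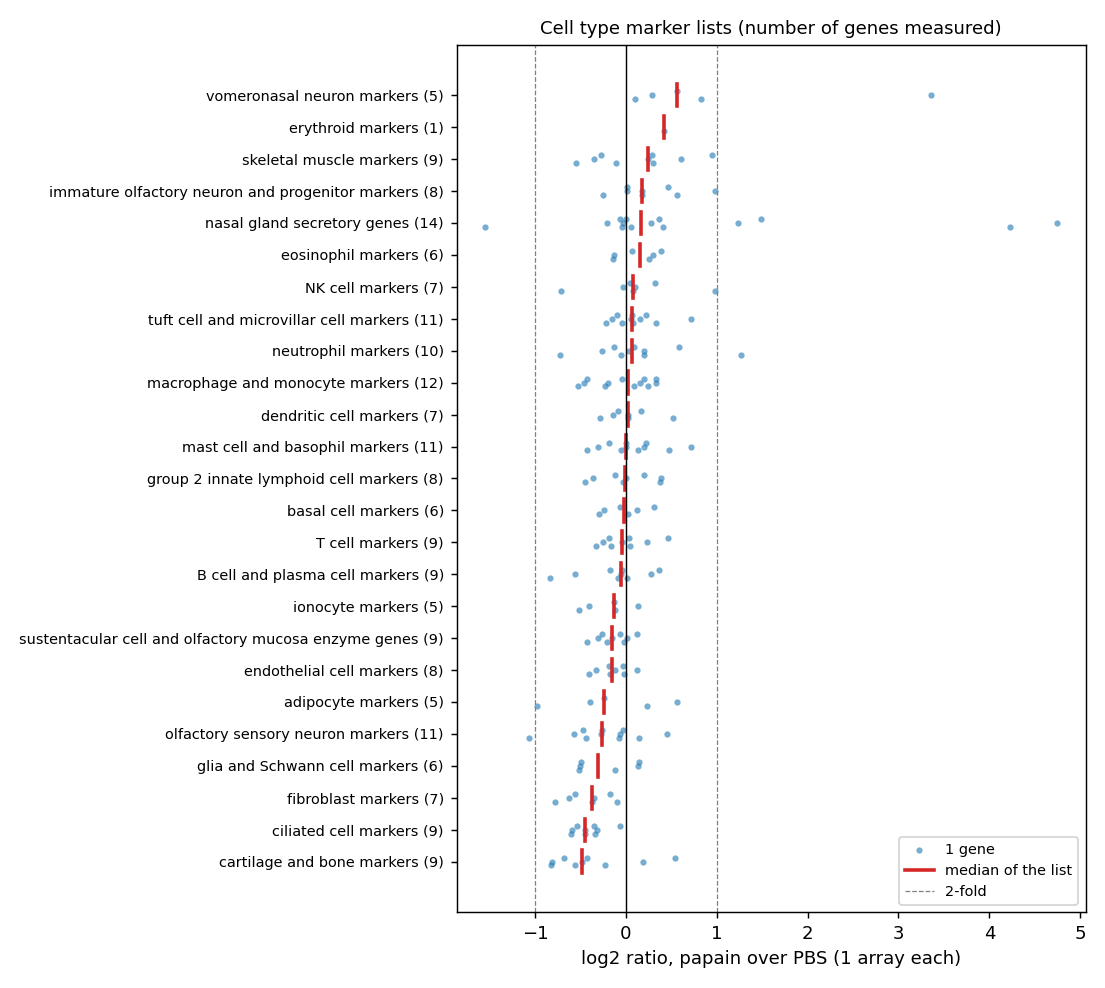
Log2 ratio of papain over PBS for each measured gene of the 25 cell type marker lists, 1 array per group, with the number of genes in parentheses, the list median as a red bar and 2-fold as dashed lines. All 9 ciliated cell markers and all 7 fibroblast markers lie left of 0, and all 5 vomeronasal neuron markers lie right of it.

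Across 11691 named genes above the floor, 186 were at least 2-fold higher and 45 at least 2-fold lower in the papain array. This balance turned at 1.5-fold, with 397 higher and 507 lower, where the median log2 ratio of these genes was -0.10. Of the 186 and 45 genes past 2-fold, 90 and 0 were vomeronasal receptors, 2 and 15 olfactory receptors, 8 and 1 predicted genes or small RNAs, and 0 and 3 antigen receptor segments, leaving 86 and 26 other genes. The 10 highest of these other genes were Bpifb9b, Bpifb9a, Chil4, H2-M1, Zpld2 at 14.4-fold, S100z at 13.3-fold, Calr4, Lipf, a lipase gene with a PBS signal of 4.00 under background, at 10.1-fold, H2-M10.5, and Calb2, a neuronal calcium-binding protein, at 6.61-fold. The 10 with the highest PBS over papain ratio were Ambn, an enamel matrix protein with a papain signal of 4.60 under background, at 3.26, Bpifb3 at 2.93, Car3, a carbonic anhydrase, at 2.84, Osr1 at 2.70, B3gnt9 at 2.61, Npy1r at 2.54, Chrdl1, an antagonist of bone morphogenetic proteins, with a log2 ratio of -1.32, Cyp4a29 at 2.36, Ifitm5, a bone gene, at 2.27, and Calb1 at 2.26. The 2 brightest probe sets went the same way for 9 of 11 genes past 2-fold with 2 or more probe sets, and for 622 of all 1082 such genes, which measures probe set error and not the spread between animals.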

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

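Among the tests in this part, the one of cross-hybridisation was chosen after the receptor medians had been seen, so it can only exclude. A signal was present in probe sets that no comparison used. Of the transcript clusters with no gene name, 170 were above the floor and at least 2-fold higher in the papain array, and 118 were at least 2-fold lower. Of the clusters with several gene names, 89 were at least 2-fold higher, in 50 distinct pairs of values, and 2 were lower. A vomeronasal receptor stood among the genes of 57 of these 89 clusters. Another 4 of the 89 listed only genes of small proline-rich proteins, cornified envelope precursors, with log2 ratios from 2.02 to 3.54. Sprr2a3, the planned keratinization list member that was not measured alone, was among these genes. Small RNA genes were named by others, Snord116l1 by 16 clusters and Rnu1b1 by 9. All Snord116l1 clusters shared the same pair of values, with a log2 ratio of 1.60, and so did those of Rnu1b1, with 1.08. These clusters are therefore no separate measurements.

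Vomeronasal receptors were higher in the papain array in both families. A trend with signal between the arrays, such as the authors' normalization could leave, is argued against, since the median log2 ratio of all 289 receptors was 1.73 as deposited and 1.70 after loess. Cross-hybridisation from 1 family as the whole cause is argued against as well, since the lower of the family medians, that of Vmn1r, was 1.45 and the families are unrelated in sequence. Vomeronasal organ tissue in the papain specimen and little in the PBS specimen stays open: 24.2% of the receptors passed the 95 percentile of 33 genes of other tissues in the papain array against 0.692% in the PBS array, short of the 50% set beforehand. Induction of the receptors by papain in an organ present in both specimens stays open too, because treatment and specimen coincide and the PBS share of 0.692% gave no sign of the organ there.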

How the results depend on the processing

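With no replicates, a median was taken as kept when it stayed inside the 95% interval from resampling its genes, and the list medians followed most closely were chosen after first medians had been seen. Of the 40 alternative values of these medians, 36 were kept and 4 moved. For the remaining lists and families, 167 values were kept, 6 moved and 2 turned sign. A sign change inside a wide interval, as for the junction median, counted as kept. A named gene's value was kept when it stayed on the same side of 2-fold, so a ratio under 2-fold could change sign. By that rule 515 values of named genes were kept, while 4 crossed 2-fold. Restricting lists to members above the floor moved Olfr to -0.24, Vmn1r to 3.57 and Vmn2r to 4.15. Type 2 cytokines and chemokines moved to 0.76, the median of only 2 genes, Ccl8 and Ccl11. The floor acts on the higher of the 2 arrays, so it keeps vomeronasal receptors because they were high after papain. Ccl8, with a PBS signal of 5.54, was kept in the same way. These larger values are no stronger evidence. The eicosanoid median turned to -0.030 with averaged probe sets and -0.20 above the floor; the cause was not tested. Genes at least 2-fold higher numbered 405 without a floor, 93 with a floor at the 75 percentile, 397 at 1.5-fold and 86 without families, predicted genes and small RNAs. Genes lower numbered 162, 18, 507 and 26 in the same order and 6 at 3-fold. The excess of higher genes turned into an excess of lower ones at 1.5-fold. Quantile normalization and loess took Fabp4 to -1.04 and -1.03 and Gng8 to 1.05 and 1.08. No paired analysis was possible because each group was 1 array. Signals near those of genes of other tissues limit what can be read for Il5, Il13 and the eosinophil markers.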

Other observations

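Among the tests in this part, those of eosinophils and macrophages and of even dilution were chosen after the list medians had been seen, and the lower lists were picked by their medians. The gene families in the next paragraph were also chosen after the data had been seen.

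Values of further chemosensory families follow. The 9 genes of the H2-M1, H2-M9, H2-M10 and H2-M11 group, which vomeronasal neurons with family 2 receptors express, had a median of 3.43-fold, with 7 at least 2-fold higher and 0 lower, from a median PBS signal of 4.43, under background. Of the 3 formyl peptide receptor-like genes (Fpr-rs), expressed by other vomeronasal neurons, 1 was past 2-fold, and their median signals of 3.73 after papain and 2.82 after PBS were both under background. Trace amine receptors (Taar) had a median log2 ratio of -0.03 over 15 genes, with 1 past 2-fold and lower. Their median signal was 5.09 after papain and 4.50 after PBS, the latter under background. The 14 exocrine gland peptide genes (Esp) had median signals of 3.73 and 3.58, under background in both arrays, and none was past 2-fold.

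The IL-4 and IL-13 response list had a higher median in the papain array, from 6 of 17 genes past 2-fold. A trend with signal between the arrays is argued against, as the list lay above all random lists matched on mean signal. It stayed at the 100 percentile after loess, which adds little because the matching already allows for such a trend. More eosinophils and macrophages in the papain specimen stays open: eosinophil markers had a median log2 ratio of 0.16, but 0 of 6 passed the 95 percentile of genes of other tissues, 6.98, in the PBS array. Macrophage markers were all above the floor and showed no common gain, with a median of 0.03 and an interval from resampling genes of -0.33 to 0.22, which leaves room for cells that differ in state more than in number. A response to papain may account for the list and is the hypothesis that the design names, but it was not separated from a difference between the specimens, vomeronasal tissue included.

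The fibroblast, bone, matrix and ciliated cell lists had lower medians in the papain array, with none of their 38 genes past 2-fold. Added tissue that dilutes every other cell type alike was examined as the whole cause. Among marker lists without the vomeronasal one, 13 had 3 or more members whose mean signal reached the floor. Their medians had an SD of 0.26. Shuffling the 97 genes among these lists gave a median SD of 0.17. The observed value lay at the 99.4 percentile of 10000 shuffles. It did so with the floor on the higher signal too, where the SD was 0.29. These lists thus moved apart more than shuffled genes did. Dilution of the lower lists stays undecided, because shuffling ignores that genes of a list can vary together. The lists also held neuron markers that added vomeronasal tissue could itself bring. A trend with signal as the whole cause is argued against, since the median of the 4 lower lists was -0.44 as deposited and -0.37 after loess. A different cut of bone and respiratory epithelium between the specimens, and an effect of papain on these cells, both remain possible and were not tested.

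Further hypotheses were tested without a decision. Dbp, a clock output gene, had a log2 ratio of -0.83, and a different phase of the day at collection was examined: the 8 other genes that peak with Dbp had a median of -0.25, short of the -0.3 set beforehand, and -0.37 with Dbp included. The 5 genes in antiphase had -0.02, not the 0.2 or more set beforehand. The bound against this explanation, antiphase genes moving down, was first read from the median alone, which would have ruled it out; after that value was seen, its resampled interval, which reached 0.38, was required to lie below 0. For the olfactory receptors, a different share of the dorsal zone, where class I receptors are expressed, was examined. The class I median exceeded that of class II by 0.19, with an interval of 0.11 to 0.36, between the bounds set beforehand. The median signal of all Olfr genes was under background in both arrays, which limits this comparison. A different sex composition of the specimens was examined as well: Xist read 10.64 after papain and 10.23 after PBS, and 3 Y-linked genes were under background in both arrays, at most 4.47 and 3.99, so their median ratio of 0.48 is no measure of transcript. Neither array thus gave a sign of male tissue, but no sample of known sex was at hand to show what these probe sets read in males.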
